A study of Caenorhabditis elegans with 2 samples.

How the data were processed

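In situ Hi-C was made on nuclei of mixed-stage embryos of 2 strains, with the enzyme DpnII, per the labels' protocols. Per the series' design text there were 3 biological replicates of met-2 set-25 and 2 of cec-4. The aligner, the read filters, the balancing method and the insulation window are not given in the sources used here. Coordinates are on ce11, per the submitters' processing notes and the bin names.

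The deposited contact signal is a symmetric matrix of 2008 bins of 50 kb per genotype, in which each row with full data sums to 504 and the whole to 1000000. The diagonal and the next diagonal hold 0, so the shortest usable pair spans 100 kb. All values were whole multiples of a step that fits means of 3 and of 2 maps (tolerance 0.01 of a step), so the deposited signal is a mean over replicates that could not be separated. Since the values are balanced, rows cannot differ in total, and a region with more contact inside its chromosome has less outside it. The deposited z-score matrices were made with cworld-dekker 0.41.1, with cisAlpha 0.01 and cisApproximateFactor 1000, per the file headers. The 2 z-score files were written in separate runs of that tool, per the file headers. The squares of the deposited eigenvector score sum to 1 over the genome, as in a single genome-wide decomposition, but its method is not given in the sources used here and was not recovered. The fraction of variance of the first eigenvector, as deposited, corresponds to 62.7% in met-2 set-25 and 69.4% in cec-4. Its sign is arbitrary (r of -0.979 between the genotypes as deposited), so that of met-2 set-25 was turned to make autosome centres positive. It was then standardised to mean 0 and SD 1 over the genome. The deposited insulation score was used unchanged.

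Bins that were empty or held data of only some replicates in either map (21 and 22 empty, 7 and 4 partial) were left out, which left 1979. Each chromosome was divided into a left, a centre and a right section of equal length, and the outer sections of the autosomes are called arms. Arm compaction is the mean over distances of the log2 ratio of contact within arms to contact within the centre. Inter-arm preference is the same for contact between the left and right arm over contact between arm and centre. A distance was used where each class held at least 20 pairs. Compartment strength is the log2 ratio of observed over expected contact of like bins to that of unlike bins, with 20% of bins at each end of the eigenvector and pairs 500 kb or more apart. The preference between chromosomes is the log2 ratio of the geometric mean of arm-arm and centre-centre contact to arm-centre contact. Insulation minima were the lowest bin within 250 kb on either side and at least 0.1 below the median of that window, and counted as shared within 1 bin.

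Genes were placed in bins through the RefSeq table of assembly WBcel235, which has the coordinates of ce11. Fixed before the data were examined were 24 gene lists, of which 1 (transposon genes) matched no gene, the measures, and the rule for named genes. The rule took the mutated genes, the landmark genes, up to 10 runs of at least 2 adjacent bins that differ by 0.5 or more, and the 3 deepest and 3 most different insulation minima on X and on the autosomes. Up to 3 genes nearest the middle name each place. List medians were ranked among 10000 random bin sets matched on chromosome and on centre or outer section, with left and right pooled.

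With 1 map per genotype no test was made. The measures were tested on simulated maps of 2008 bins with planted values. The largest error of the arm measures was 0.0039 on the log2 scale, a planted compartment strength of 0.5 was returned as 0.475, and 100% of 9 planted boundaries were found. The strength was planted as alternating blocks and the boundaries on chromosome V. Both were scored with an eigenvector and an insulation score computed from the simulated map. The deposited eigenvector and insulation score were therefore not checked. Alternatives covered arm limits (narrower arms, and limits of the recombination domains written from memory and not checked against a genetic map), medians, distances, eigenvectors, minima and each autosome left out. An eigenvector computed per chromosome was run first. A genome-wide one was added after the first had been seen to give strengths near or below 0 on several chromosomes, and both are reported. They correlated with the deposited eigenvector at 0.551 and 0.539 in met-2 set-25 and at 0.649 and 0.889 in cec-4, respectively. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The planned relation of the eigenvector to repeats needs a genome sequence and was not run.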

Results

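Contact maps of Caenorhabditis elegans embryos of mixed stage were compared between 2 genotypes. The met-2 set-25 double mutant lacks MET-2 and SET-25, the methyltransferases that together make H3K9 methylation in embryos, and the cec-4 mutant lacks a chromodomain protein of the inner nuclear membrane that holds H3K9-methylated chromatin at the nuclear periphery. The comparison addresses which features of chromosome folding differ between loss of the methylation and loss of its anchor. Per the series' design text, 3 biological replicates of met-2 set-25 and 2 of cec-4 were made. The deposited files hold 1 averaged map per genotype at 50 kb resolution on ce11, so no difference could be set against the spread between replicates, and no test was made. Each value ± SD below gives the spread between the 5 autosomes, or between the 10 pairs of autosomes for contact between autosomes. For a difference it is the spread of the difference. Autosomes and their pairs are not replicates. A wild-type map was not analysed here. The files are balanced values and not read counts, so the sequencing depth is unknown.

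Chromosomes of met-2 set-25 embryos made more of their contacts with themselves, and more of these at short distance, than chromosomes of cec-4 embryos. Contact within chromosomes made up 68.8% of the map in met-2 set-25 and 59.2% in cec-4, and the share was higher in met-2 set-25 on 5 of 5 autosomes and on X (70.2% against 59.8%). At a distance of 100 kb, autosomal contact was 11.4 ± 0.66 in met-2 set-25 and 7.37 ± 0.38 in cec-4, which is 1.55-fold higher. The ratio was 1.17-fold at 500 kb, 1.13-fold at 1000 kb, 1.17-fold at 2000 kb and 1.03-fold at 5000 kb, and at 10000 kb contact was lower in met-2 set-25, at 0.884 of the cec-4 value. The curves crossed between 5.35 Mb on chromosome IV and 5.8 Mb on chromosome V, and at 4.45 Mb on X. At 10000 kb autosomal contact was 0.20 in met-2 set-25 and 0.23 in cec-4. Mean contact between chromosomes was 0.095 and 0.125, respectively. The curves were not compared with that mean removed, so the lower contact at long distance and the crossing points may depend on it.

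**Figure D1:**
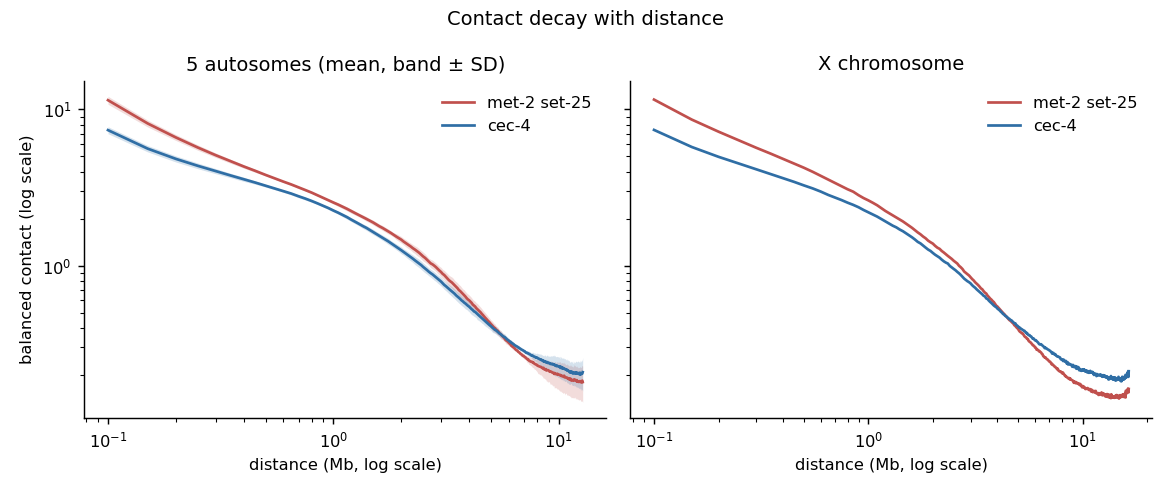
Balanced contact (log axis) against distance in Mb (log axis), for the 5 autosomes (line, mean; band, ± SD between autosomes) and for X, in met-2 set-25 (red) and cec-4 (blue). The red line starts at 11.4 and the blue at 7.37 on the autosomes, and the lines cross above 5 Mb there and at 4.45 Mb on X.

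The share of contact within chromosomes that spanned 1 Mb or more was 54.1 ± 2.8% on the autosomes of met-2 set-25 and 57.8 ± 2.86% on those of cec-4. The difference was -3.69 ± 0.33 percentage points and had the same sign on 5 of 5 autosomes. It was larger on X, which carries the dosage compensation machinery in hermaphrodites, where the share was 51.7% against 58.0%. When pairs closer than 250 kb were left out, the autosomal difference was -1.92 points, and it was -2.19 points with the mean contact between chromosomes removed, a setting chosen after seeing the data.

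In both genotypes the arms of the autosomes, where H3K9 methylation is concentrated in wild-type embryos, were more compact than the centres. Contact within arms exceeded contact within the centre at the same distance on 10 of 10 autosome arms in each map. The log2 ratio of arm to centre was 0.19 ± 0.077 in met-2 set-25 and 0.23 ± 0.085 in cec-4. It was lower in met-2 set-25 on chromosomes I, II, IV and V, with values of -0.064, -0.076, -0.015 and -0.034 for the difference, and not on chromosome III (0.0026). The mean difference was -0.037 ± 0.033. With narrower arms it was -0.086 ± 0.039, lower in met-2 set-25 on 5 of 5 autosomes. Limits approximating the recombination domains, which were written from memory and not checked against a genetic map, gave -0.081 ± 0.037, with 5 of 5 autosomes and 9 of 10 arms lower. With those limits the largest gap lay on the right arm of chromosome V, at 0.24 in met-2 set-25 and 0.43 in cec-4. On X the ratio was 0.11 and 0.13, and the left section of X was close to its centre in both maps (0.026 and 0.032).

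The preference of the left and the right arm of the same autosome for each other was slightly higher in met-2 set-25. Contact between them relative to contact between arm and centre at the same distance was 0.019 ± 0.15 in met-2 set-25 and 0.0012 ± 0.14 in cec-4 on the log2 scale. The difference of 0.018 ± 0.014 had the same sign on 5 of 5 autosomes and was smallest on chromosome I (0.0010). It was 0.107 with narrower arms and 0.115 with the unchecked limits of the recombination domains. With the mean contact between chromosomes removed, a setting chosen after seeing the data, it was 0.079, and 0.603 with those limits as well, so its size is not settled. Chromosome III stood apart from the other autosomes, with 0.26 in met-2 set-25 and 0.23 in cec-4, whereas chromosomes I, IV and V were below 0 in both maps.

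**Figure D2:**
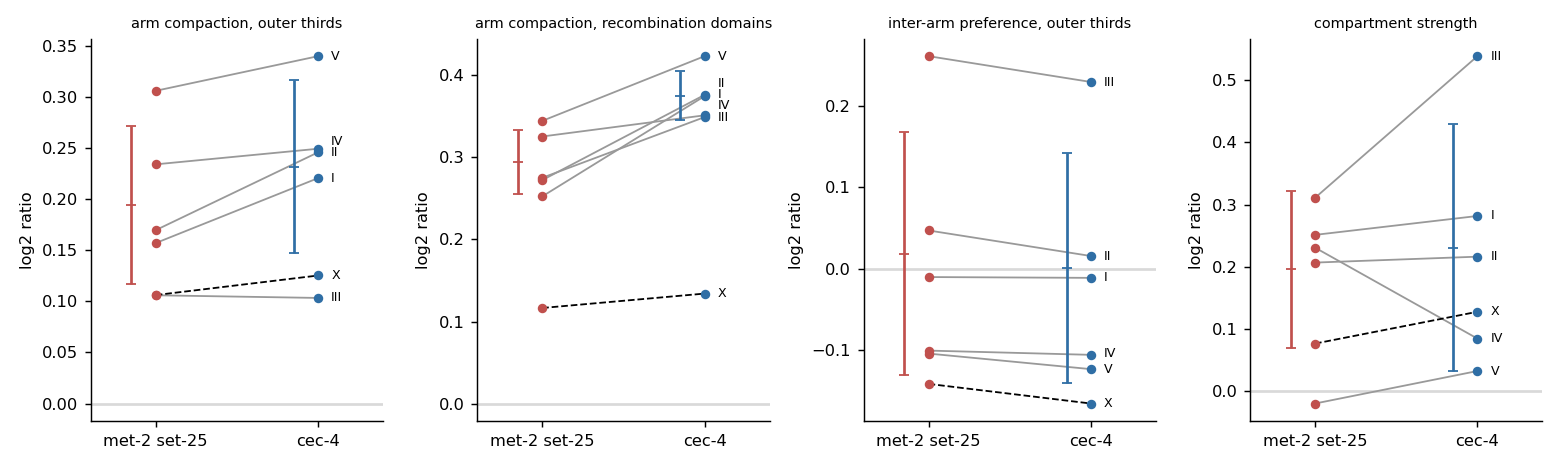
Log2 ratios per chromosome in met-2 set-25 (red) and cec-4 (blue), with lines joining the same chromosome (dashed for X) and bars for the mean ± SD over the 5 autosomes. Panels show arm compaction with sections of equal length and with the unchecked limits of the recombination domains, inter-arm preference and compartment strength. Arm compaction with recombination domains is higher in cec-4 on 5 of 5 autosomes, and compartment strength moves in opposite directions on chromosomes III and IV.

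Between different autosomes, arm-arm contact was lower in met-2 set-25 (0.104) than in cec-4 (0.129), as was mean contact between chromosomes, but relative to arm-centre contact it was higher. The log2 ratio of arm-arm to arm-centre contact was 0.25 ± 0.021 over the 10 pairs of autosomes in met-2 set-25 and 0.13 ± 0.018 in cec-4, and it was higher in met-2 set-25 in 10 of 10 pairs. The ratio for centre-centre contact was 0.26 ± 0.10 and 0.27 ± 0.11, and it was higher in met-2 set-25 in 4 of 10 pairs. The combined preference of like for like was 0.251 in met-2 set-25 and 0.194 in cec-4 over all autosomal pairs of bins. The difference in this combined preference was lost when both maps were set to the same mean contact between chromosomes (-0.0020). That setting was chosen after seeing the data. The preference averages the arm-arm and the centre-centre ratio, which were not recomputed singly at that setting and may differ in opposite directions. The value thus does not show that the arm-arm difference was lost.

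The X chromosome met autosome arms relatively more with its ends in met-2 set-25 than in cec-4. Its right section met autosome arms more than centres in met-2 set-25 (0.093 on the log2 scale) and equally in cec-4 (-0.00062). The left section of X gave 0.039 and -0.048. The centre of X met autosome centres more than arms in both maps, with -0.20 and -0.22. These are ratios of contact with arms to contact with centres and not the preference of like for like. They also depend on how much contact arms and centres make outside their own chromosome. They were not recomputed with equal mean contact between chromosomes.

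The deposited compartment profiles were alike in both genotypes. The deposited first eigenvector, turned so that autosome centres are positive and standardised over the genome, correlated between the genotypes with a mean r of 0.981 over the 6 chromosomes, from 0.959 on V to 0.994 on III. The mean r was 0.587 and 0.342 with eigenvectors computed here per chromosome and genome-wide, which followed the deposited ones incompletely, and 0.988 for a measure without an eigenvector that was chosen after seeing the data, the contact of each bin with centres over arms of other chromosomes. These are correlations across bins of 1 map per genotype, and neighbouring bins are not independent. Of 1979 bins, 111 (5.61%) had opposite signs. Of these, 62 lay on X, 22 on IV, 21 on V, 3 on I, 2 on II and 1 on III. Compartment strength, the contrast of like against unlike bins at 500 kb or more, was 0.20 ± 0.13 in met-2 set-25 and 0.23 ± 0.20 in cec-4. With this deposited eigenvector too, strength was near 0 on chromosome V (-0.019 in met-2 set-25 and 0.033 in cec-4), and it was 0.085 on IV in cec-4. The difference of -0.035 ± 0.13 was within the spread between autosomes. It was -0.23 on chromosome III and 0.15 on chromosome IV, and it turned to 0.013 without chromosome III and to 0.15 and 0.050 with eigenvectors computed here per chromosome and genome-wide.

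**Figure D3:**
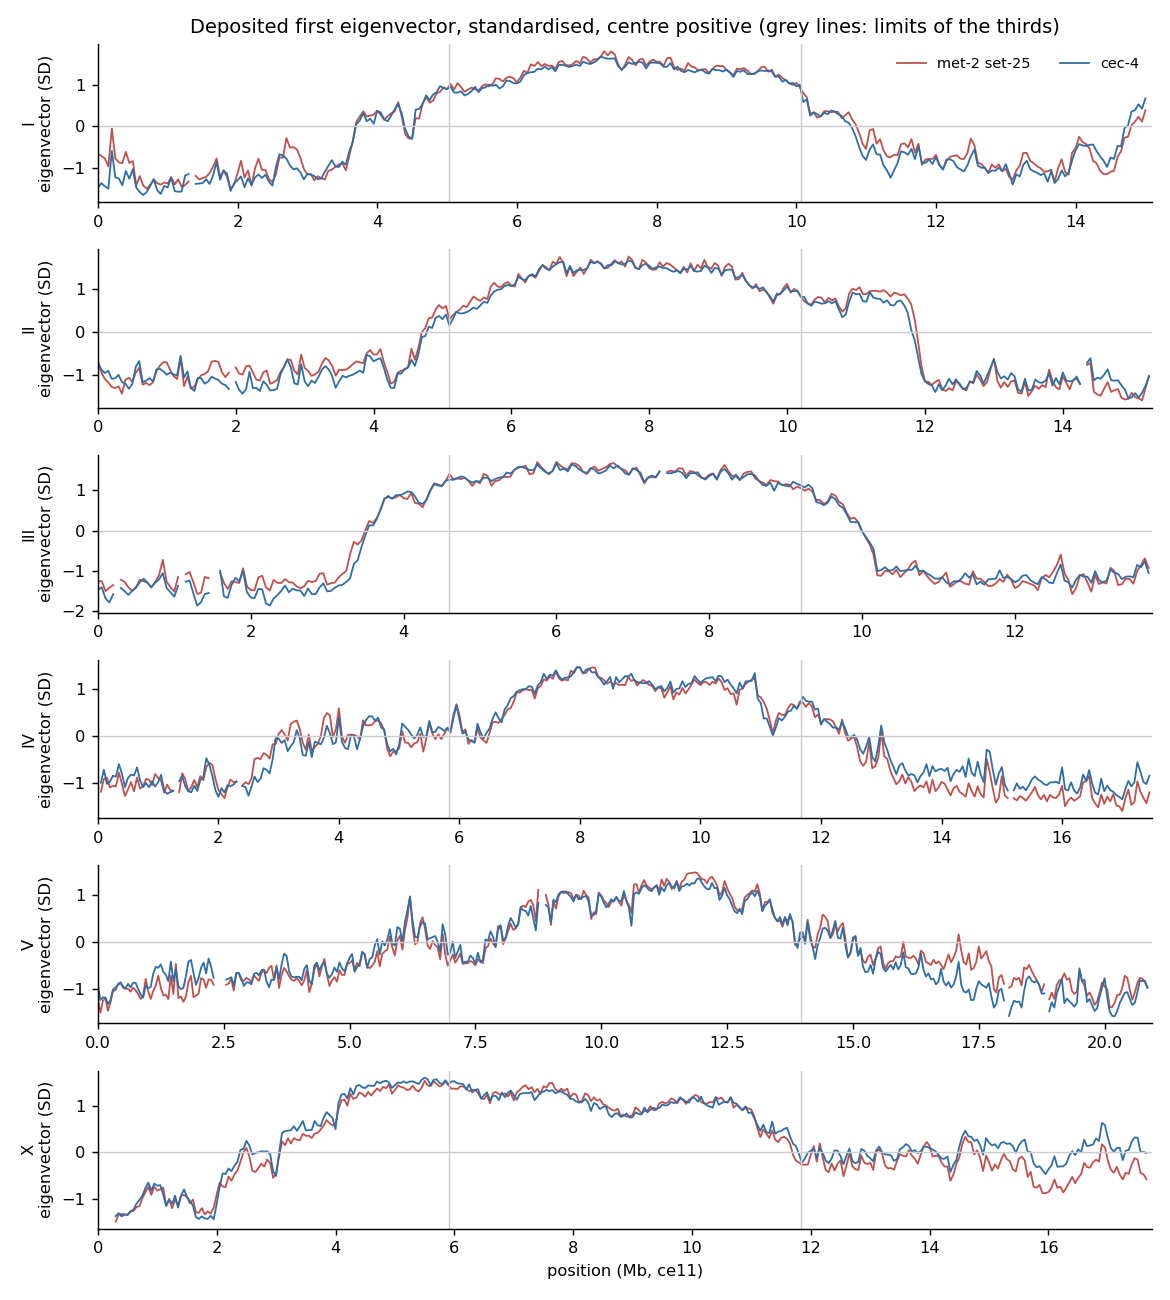
Standardised first eigenvector (SD units, centre positive) against position in Mb on ce11, for each chromosome in met-2 set-25 (red) and cec-4 (blue), with grey lines at the limits of the left, centre and right sections. The lines run together on most of the genome and part on the right sections of X (means -0.27 and 0.024), IV (-0.87 and -0.62) and V (-0.51 and -0.76).

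The right section of X, the right section of IV and the right section of V differed most among the sections. On X the mean was -0.27 in met-2 set-25 and 0.024 in cec-4, and 12.8% and 59.0% of its bins lay above 0. On IV the means were -0.87 and -0.62, and on V -0.51 and -0.76. The X difference of -0.30 changed sign with eigenvectors computed here per chromosome (0.046) and genome-wide (0.079), and the IV difference of -0.24 with the genome-wide one (0.048). The V difference of 0.24 kept its sign with both, with sizes of 0.27 and 1.96. The genome-wide one was positive on all 3 sections, so its sign does not set V apart. Without an eigenvector, standardised contact with centres over arms of other chromosomes differed in the main direction on all 3, by -0.046 on X, -0.16 on IV and 0.073 on V.

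Only 4 runs of adjacent bins differed by 0.5 or more throughout. The left tip of chromosome I, from 1 to 250000, stood at -0.64 in met-2 set-25 and -1.29 in cec-4. It holds spe-8, a sperm kinase gene, mex-3, which encodes an RNA-binding protein of the early embryo, and the collagen gene col-45. On chromosome V, 850 kb from 16850001 to 17700000 stood at -0.31 and -0.94. Near its middle lie the F-box gene fbxa-85 and the chemoreceptor genes srh-115 and srh-116. On X, the stretch from 16250001 to 16550000 stood at -0.67 and -0.095 and holds eat-17, the type IV collagen gene let-2 and sur-7. On chromosome III, the stretch from 3300001 to 3400000 stood at -0.43 and -1.0, at gei-1, prk-2 and phf-15.

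Gene families of the arms differed unequally between the genotypes. F-box genes encode substrate adaptors of ubiquitin ligases, and 95.1% of their 143 bins lie in the outer sections of autosomes or X. Their median over these bins was -0.76 in met-2 set-25 and -0.97 in cec-4. The median difference of 0.14 was above all of 10000 random bin sets matched on chromosome and on centre or outer section. MATH and BTB genes differed by 0.13 (37 bins, percentile 99.5) and C-type lectin genes by 0.087 (132 bins, percentile 99.99). The percentiles describe these maps and are no p-values, since neighbouring bins move together. The match pooled left and right sections, which on V differed by -0.13 and 0.24. A list that lies mostly on a single side can thus rank at an extreme by position alone. The chemoreceptor genes, over 421 bins, differed by 0.014 (percentile 78.0) and nuclear hormone receptor genes by -0.012 (percentile 30.1). Detoxification enzyme genes differed by -0.043 (percentile 0.17). The piRNA genes differed by -0.027, below all random sets, or by -0.27 when each gene and not each bin was counted once. Chromosome IV holds 14561 piRNA genes and no other chromosome more than 202, so the value per gene mostly reflects IV. The right section of IV differed by -0.24. With eigenvectors computed here per chromosome and genome-wide, the F-box difference was 0.15 and 0.99 and that of MATH and BTB genes 0.37 and 0.39. Both kept their sign, but their size is unsettled. The C-type lectin, chemoreceptor, nuclear hormone receptor and detoxification lists each changed sign with either the former or the latter. The genome-wide one gave positive values for these lists too (0.56, 1.15, 0.96 and 0.70). Its sign thus does not set F-box or MATH and BTB genes apart.

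Several gene families had positive medians in both maps. The median was 0.32 and 0.35 for ribosomal protein genes, 0.85 and 0.81 for proteasome genes, and 1.04 and 0.95 for genes of respiratory complex I and ATP synthase. Collagen genes had 0.67 and 0.64, histone genes 0.76 and 0.66, and major sperm protein genes 0.52 and 0.33. The median difference per bin was in part of the other sign, at 0.0012 (percentile 12.7) for ribosomal protein genes, 0.038 (55.4) for the proteasome, -0.0089 (7.29) for complex I and ATP synthase, -0.015 (6.79) for collagens, 0.018 (64.4) for histones and -0.019 (39.96) for major sperm proteins. Of these, the last alone kept its sign with both eigenvectors computed here. The tRNA genes had medians of -0.13 and 0.040, but a median difference of -0.000089 (percentile 89.9), which was 0.0026 when each gene was counted once. Of the 20 lists with at least 5 bins, 11 had a lower median difference in met-2 set-25.

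All landmark genes but myo-2 and the heterochromatin gene hpl-1 (-0.034 and 0.0092) had values of the same sign in both maps. The Hox genes of the centre of chromosome III, which pattern the body axis, stood high in both maps, with 1.49 and 1.43 at lin-39 and 1.46 and 1.43 at egl-5, and the posterior Hox gene nob-1 on the right section stood low (-1.38 and -1.23). The muscle myosin gene myo-3 had 1.4 and 1.27, unc-54 near the right end of chromosome I had 0.11 and 0.39, and the pharyngeal myosin gene myo-2 on X had -0.25 and 0.040. The endoderm regulator elt-2 had 1.17 and 1.03, the vitellogenin gene vit-2 1.42 and 1.51, and the foregut regulator pha-4 -0.78 and -0.83. Among germline genes, mex-3 differed most (-0.78 and -1.46), and glp-1 had 1.14 and 1.10. The lamin gene lmn-1 had 1.29 and 1.27, and the emerin gene emr-1 -1.07 in both maps. The mutated genes themselves lay in the same compartments in both maps. The values were 1.35 and 1.39 at met-2, -0.92 and -0.97 at set-25 and 1.23 and 1.29 at cec-4. Balanced values at 50 kb do not show whether a gene is deleted, so the maps do not check the genotype labels.

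Insulation, the drop of contact across a bin, was most alike on X. The deposited score correlated between genotypes with r of 0.973 on X and with 0.913 ± 0.024 on the autosomes, lowest on chromosome I (0.880). The SD of the score along the autosomes was 0.190 in met-2 set-25 and 0.216 in cec-4, and along X 0.177 and 0.178. Local minima numbered 25 in met-2 set-25 and 23 in cec-4. On X, 6 of 7 in each map had a partner within 1 bin in the other, and on the autosomes 10 of 18 and 10 of 16 did. Together 66.7% were shared, against a mean of 3.39% and at most 20.8% after 1000 circular shifts of one map. The share was 54.2% when the same bin was required and 79.2% within 2 bins.

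The deepest X minimum in both maps lay at 11750001 to 11800000, by the LIM homeobox gene ttx-3, lact-7 and rsd-3, with depths of 0.26 and 0.23. Minima at 2000001 by ergi-1 (0.20 and 0.19), at 3000001 by aqp-7 and flp-18 (0.19 and 0.17) and at 4050001 by clh-4 (0.18 and 0.19) followed. The X minimum that differed most lay at 7050001 by pdi-6, ubc-17 and hen-1, with 0.17 and 0.10, followed by that at 5000001 by sek-3 (0.16 and 0.13). On the autosomes the deepest minimum in met-2 set-25 and in cec-4 was at 10900001 on chromosome I, by cpn-4 and prp-17 (0.26 and 0.24). Next in met-2 set-25 came 11050001 on IV by atg-7 and let-70 (0.23 in both) and 10200001 on I by ced-12 and lin-11 (0.20 and 0.14). Next in cec-4 came 10950001 on IV by aqp-3 and cyb-2.1 (0.18 and 0.24) and 2800001 on IV by clec-80 and pudl-1 (0.11 and 0.15). The places at 10950001 and 11050001 on IV lie close together and were low in both maps, so they may be a single valley. The largest difference lay at 3300001 on chromosome III by phf-15, ral-1 and gei-1, with 0.18 and 0.034, in the stretch whose compartment value also differed. The heterochronic gene lin-29 marked the next, at 11900001 on chromosome II (0.18 and 0.11), and at 1550001 on II, by math-38 and fbxb-46, the minimum was deeper in cec-4 (0.076 and 0.14).

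**Figure D4:**
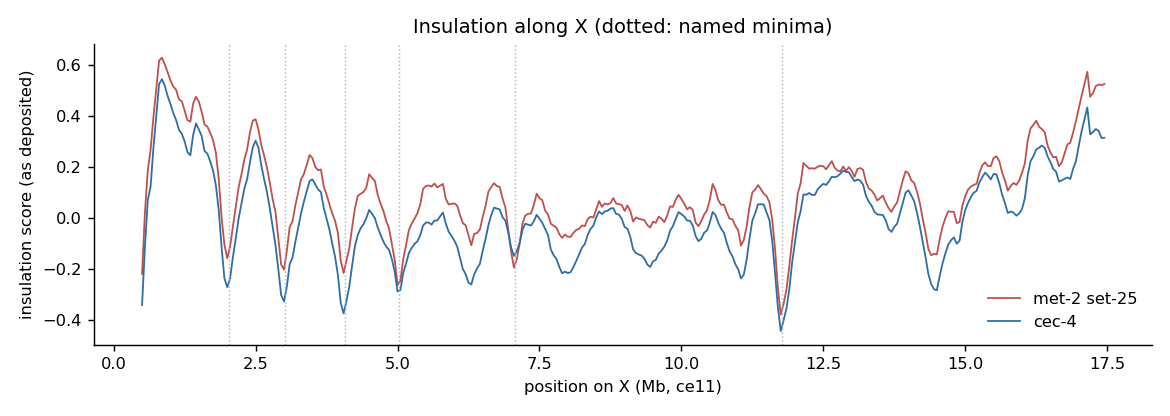
Deposited insulation score against position on X in Mb (ce11) in met-2 set-25 (red) and cec-4 (blue), with dotted lines at the named minima. The deepest minimum, at 11750001, has depths of 0.26 and 0.23, and the lines follow each other with r of 0.973.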

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

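Of 138 alternative values, 74 moved by less than their spread, 33 by more without a change of sign, and 27 changed sign. Beside these, 3 counts of lists stayed within 1.5 times and 1 value was in another unit. The sign rule was applied to all values, near 0 or not. For the right sections the spread was the SD of the difference over bins. For the gene lists it exceeded every main difference, so a move within it says little on stability. For ribosomal protein genes a move from 0.0012 to 0.16 stayed within a spread of 0.18. The genome-wide eigenvector, the removal of contact between chromosomes, the combined settings and trans contact with centres over arms were chosen after seeing the data. So were all alternatives for the right sections and the cis share over bins with full data only. The cause of these changes was not tested. Arm compaction differed by -0.081 with recombination domains (limits unchecked), -0.086 with narrower arms and -0.10 with domains and the trans mean removed. Inter-arm preference differed by 0.115, 0.107 and 0.603 in the same order, and by 0.079 with the trans mean alone removed. The long-range share differed by -3.34 points from 2 Mb, -1.92 from 250 kb and -2.19 with the trans mean removed. Trans preference differed by 0.048 with medians and by -0.0020 with equal trans means. Compartment strength differed by 0.15 with the eigenvector computed per chromosome, 0.050 with the genome-wide one, 0.013 without chromosome III, and -0.091 in z-score units. Profile similarity was 0.954 by Spearman, 0.942 within arms, 0.964 within centres, 0.587 with the eigenvector computed per chromosome and 0.342 with the genome-wide one. It was 0.988 for trans contact with centres over arms, which uses no eigenvector.

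With the eigenvector computed per chromosome, signs changed for chemoreceptors (-0.18), C-type lectins (-0.064), complex I and ATP synthase (0.088), histones (-0.054), collagens (0.044), Hox genes (-0.083), germline genes (-0.17), dosage compensation genes (0.18), heterochromatin factors (0.021) and the right section of X (0.046). With the genome-wide one they changed for nuclear hormone receptors (0.96), detoxification enzymes (0.70), ribosomal proteins (-0.97), proteasome (-0.90), histones (-0.42), Hox genes (-0.54), muscle genes (0.19), gut genes (0.81), germline genes (-0.93) and the right sections of X (0.079) and IV (0.048). Counting each gene once changed the sign for ribosomal proteins (-0.0038) and tRNA genes (0.0026) and moved piRNA genes to -0.27.

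Not run were thinning, another balancing, pairs from 50 kb and the diagonal, which the balanced files do not allow, and the relation to repeats. Outside the 2 blanked diagonals no pair of bins with full data was empty within chromosomes, and 2 pairs between chromosomes were in each map. No bin was left out for empty cells, so that setting moved nothing. Sequencing depth is unknown, so what it limits could not be stated.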

Other observations

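The tests in this part, other than the planned narrower arms, were chosen after the results had been seen.

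The deposited gene density ran against the compartment value on chromosome IV alone, with r of -0.51 in met-2 set-25 and -0.41 in cec-4 across bins. On that chromosome the deposited density correlated at 0.982 with the number of piRNA genes, of which it holds 14561, and protein-coding genes correlated with the compartment value at 0.42 in both maps. The 15 ribosomal RNA genes of chromosome V lie between 17115903 and 17428996, inside the 850 kb stretch whose compartment value differed between the genotypes. Over the last 10 used bins of each chromosome, the left end of I (-0.73 and -1.27) and the right end of X (-0.40 and 0.092) differed most. The right end of IV followed with -1.30 and -0.96.

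The steeper decay in met-2 set-25 could come from random contact added evenly to the cec-4 map. The share of contact within chromosomes sets that random contact at 18.6%, which predicts 9.36 ± 0.54 at 100 kb in cec-4. The observed contact was lower on 5 of 5 autosomes, with a mean difference of -2.0 ± 0.20, so even random contact cannot be the whole account. Separate libraries per genotype cannot be told apart from genotype, with 1 deposited map of each and the replicates averaged. A difference of the mutations themselves also stays open, and without a wild type the maps do not say which genotype departs from normal folding.

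The lower arm compaction in met-2 set-25 goes against even random contact in cec-4, which would lower the cec-4 ratio. At 18.6% it predicts 0.18 ± 0.069 where 0.23 ± 0.085 was observed, a difference of 0.048 ± 0.034, above 0 on 5 of 5 autosomes. Since even contact lowers a ratio above 0, a gap in this direction was fixed once the cec-4 mean was seen to be higher. Without the model the ratio was higher in cec-4 on 4 of 5 autosomes. Placement of the arm limits does not account for the lower arm compaction either, since narrower arms gave -0.086 ± 0.039, lower on 5 of 5 autosomes. A difference of the mutations themselves was not tested and stays open, as do library differences.

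For the higher trans arm preference in met-2 set-25, random contact at 18.6% predicts 0.16 ± 0.043 in cec-4, where 0.20 ± 0.060 was observed. The observed value was higher by 0.038 ± 0.018, with 10 of 10 pairs of autosomes above the prediction. That prediction overshoots the gap to met-2 set-25 (0.255), so it does not count against random contact as a cause. A share of 9.89% meets the preference itself but predicts 0.21 ± 0.087 for the log2 ratio of centre-centre to arm-centre contact in cec-4, and 0.27 ± 0.11 was observed. That difference was 0.063 ± 0.025 and above 0 in 10 of 10 pairs, so at that share even random contact is not the whole account of both ratios. The difference in the combined preference was lost with equal mean contact between chromosomes (-0.0020). The ratios that it averages were not recomputed there and may differ in opposite directions. That value thus does not decide on a part for even contact, which stays open. Random contact joined with another difference was not tested. The log2 ratio of arm-arm to centre-centre contact was -0.016 ± 0.093 in met-2 set-25 and -0.14 ± 0.099 in cec-4. The cec-4 value differed by -0.13 ± 0.038 from that predicted with random contact and was lower in 10 of 10 pairs. Even contact draws this ratio towards 0, and cec-4 lay further from 0, so a gap in this direction was fixed beforehand. Balancing ties this ratio to contact inside chromosomes, which took 68.1% in arms and 69.4% in centres of met-2 set-25, and 59.2% and 58.6% in cec-4. No biological explanation of this ratio was tested.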
